A study of Mus musculus with 6 samples.

How the data were processed

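RNA was measured by bulk sequencing in 6 libraries of sorted mouse hepatocytes, 3 from GFP-negative cells (control) and 3 from GFP-positive cells (miR-206). The labels give total RNA isolated with a micro-scale column kit and libraries made with a SMARTER mRNA-Seq kit, and the design text describes ultra-low input sequencing. The deposited table holds raw counts per Ensembl gene, made by the authors, with a column for each sample. All values are whole numbers and no normalisation had been applied. The submitters' processing notes name the builds GRCm 38 and mm 10. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here, so that counts of overlapping genes and of close paralogs are uncertain. Of 49315 genes in the table, 49056 were matched by identifier to the GENCODE M21 annotation, and 174 carry no symbol and are kept under their identifiers.

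Total counts ran from 4157947 to 15244017 per library. Intervals on shares of counts are 95% Wilson intervals. For a gene at 0, the upper limit is 3 counts, which is 0.197 to 0.722 CPM (counts scaled to library size) per library. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

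Genes with enough counts by the filterByExpr defaults (minimum count 10) were normalised by TMM and tested with the edgeR 4.0.16 quasi-likelihood F test (robust fit, group as the single term) at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were compared with the other tested genes by camera in limma 3.58.1, two-sided, on log2 CPM (prior count 2) with a preset correlation of 0.01, for lists with at least 5 tested members, and adjusted over the lists. camera with an estimated correlation, rank-based camera and fry were run beside it. fry's directional p asks whether the genes of a list move on balance one way, its mixed p whether they change in either direction, and neither compares a list with other genes. Members past the gene test are counted with p adjusted over all genes tested, and adjusted over the list alone. R 4.3.3, DESeq2 1.42.0, data.table version 1.17.8, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were also used.

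The 29 lists, the tests, a first set of alternative settings and the rule for named genes were fixed before the data were examined. The lists cover miR-206 targets from the literature, lipogenesis, cholesterol synthesis, fatty acid oxidation and PPARA targets, insulin signalling and glucose output, the pentose phosphate pathway, cell cycle, hepatocyte identity, pericentral and periportal hepatocytes, bile acids, xenobiotic metabolism, male-biased genes, acute phase, interferon-stimulated genes, chemokines and cytokines, antigen presentation, immediate early and heat shock genes, unfolded protein and integrated stress response, p53 targets, fetal and injury markers, mitochondrially encoded genes, and markers of Kupffer, sinusoidal endothelial, stellate, cholangiocyte, lymphocyte, neutrophil, red cell and platelet origin. The rule named Mir206, Ttr, Ptpn1, Nr1h3 and Klf4, then the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 5 CPM and no overlap of CPM between groups, predicted genes left out, and then the 3 members of each list with the smallest p. It allowed up to 5 members for lists past the list test, and 3 were taken. With genes named more than once counted once and Mir206 left out, it gave 106 genes. Any other gene named was chosen after its values were seen. A few genes that were tested are not reported here.

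Sites for miR-206 were 8mer or 7mer-m8 matches to its seed in the longest annotated 3' UTR of each gene. Genes with a site were compared with the other tested genes that have a 3' UTR by camera, and the seed match was ranked among all sequences of 7 bases found in at least 100 genes by mean log2 fold change adjusted for UTR length. Summed CPM of each marker list was compared between groups by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1. It treats the 6 libraries as independent, although by the design text both fractions came from the same 3 mice.

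The background of each library was measured on 1702 olfactory and vomeronasal receptor genes (5503 exonic kb), which hepatocytes are not known to express. A background-corrected fit, chosen after seeing the data, subtracted the receptor counts per exonic kb times each gene's exonic length, kept nuclear protein-coding genes whose counts averaged at least 10 times that expected background, and repeated the normalisation and tests on them. The 10-fold minimum was also set to 5 and 20. Before this fit was picked, 6 other treatments were tried after seeing the data: background subtraction alone, subtraction without mitochondrial genes, scaling on the hepatocyte identity list with and without subtraction, and the 10-fold minimum on all gene types with and without subtraction. Upper-quartile, RLE and library-size scaling of the corrected fit, and a fit of the libraries with a low mitochondrial share, were added then as well. The alternatives set before the data were seen were other scalings and filters, DESeq2, limma-voom, other thresholds, mitochondrial genes left out, each library left out in turn, and the replicate number as a block. No text states that equal numbers share a mouse, so the block is an alternative and not part of the tests reported.

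The pipeline was tested on simulated data, counts with planted changes at 3 against 3 libraries. Among all genes, 34 of 87 genes planted at 4-fold and 0 of 87 at 2-fold were recovered, with 8 unchanged genes called. In the corrected fit, 44 of 95 and 3 of 99 were recovered, with 8 unchanged genes called. Few of the simulated genes were changed and all varied independently, whereas 13502 of 24382 genes passed in the data. These shares therefore do not give the sensitivity of the real tests. A planted shift of -0.3 in genes with a seed site was recovered as -0.30 and -0.25.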

Results

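Gene counts were measured in hepatocytes from 3 male C57BL/6J mice, injected at 8 weeks of age through the tail vein at high pressure with 20 µg of a transposon plasmid, in which the Ttr promoter drives miR-206 together with GFP, and 0.8 µg of a plasmid for the Sleeping Beauty transposase. After 4 weeks the cells were sorted into GFP-negative cells (control, 3 libraries) and GFP-positive cells (miR-206, 3 libraries). The sample labels name an empty vector as the treatment of the control cells, whereas the design text takes both fractions from the injected mice, and the counts do not settle which holds. Mir206 itself was counted at 0 in all 6 libraries, which allows up to 0.722 CPM in the shallowest. The libraries were made with an mRNA kit, so this count gives no measure of the mature microRNA, and the labels could not be checked on the transgene.

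The control libraries held 8966590, 15244017 and 14071679 counts and the miR-206 libraries 4157947, 4939030 and 5724329. Mitochondrially encoded genes took 36.0% (95% Wilson interval 35.9 to 36.0), 9.16% (9.14 to 9.17) and 10.4% (10.4 to 10.4) of the counts in the controls. They took 11.2% (11.2 to 11.3), 63.8% (63.8 to 63.9) and 48.7% (48.6 to 48.7) in the miR-206 libraries. Olfactory and vomeronasal receptor genes, which act in sensory neurons, gave 3.05, 1.43 and 1.26 counts per exonic kb in the controls and 5.45, 3.70 and 5.38 in the miR-206 libraries. A background at that density would account for 6.58%, 1.28% and 1.24% of the nuclear counts in the controls and 18.3%, 25.7% and 22.7% in the miR-206 libraries.

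**Figure D1:**
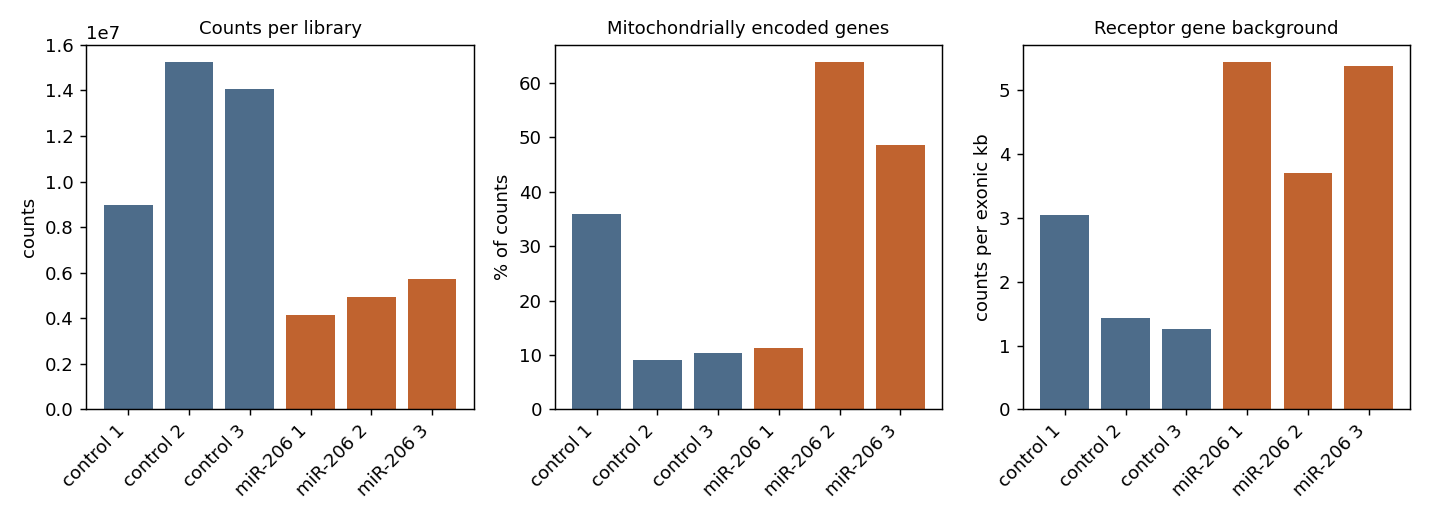
Total counts, share of counts from mitochondrially encoded genes (%) and receptor gene background (counts per exonic kb) in each of the 6 libraries, 1 bar per library, controls in blue and miR-206 in orange. The 3 miR-206 libraries hold 4157947 to 5724329 counts against 8966590 to 15244017 in the controls, and their background of 3.70 to 5.45 counts per exonic kb lies above the controls' 1.26 to 3.05.

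The comparison of miR-206 with control cells asks which transcripts differ between GFP-positive and GFP-negative sorted cells. By the design text this contrast carries plasmid uptake, GFP and the sort along with miR-206, and no library here separates them. The counts do not show whether miR-206 was raised. Transcripts of the metallothionein Mt1, a zinc- and copper-binding protein, of G0s2, an inhibitor of the triglyceride lipase Pnpla2, of Sds, a serine-degrading enzyme, and of Cyp4a10, a fatty acid hydroxylase under Ppara control, were lower in every miR-206 library than in every control, an order that 10% of genes would show in either direction by chance. So were 13 of the Kupffer cell markers, the class II antigen presentation genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74, the chaperones Hspa8 and Hsp90aa1, 14 genes of fatty acid oxidation and 14 periportal markers. All of these passed the test with the counts as deposited and after background correction. Such falls were common. With the counts as deposited 7213 of 24382 genes fell, and 1311 of the 6458 genes of the corrected fit fell in both. The counts were lower, at 8 Kupffer, 4 fatty acid oxidation and 6 periportal members, with corrected counts scaled on hepatocyte identity genes, and 10, 2 and 4 without miR-206 replicate 3. Transcripts of fibrinogen chains Fga, Fgb and Fgg, cholesterol pathway genes Hmgcs1 and Msmo1, and the lipid droplet protein Pnpla3 rose after background correction. With the counts as deposited only Pnpla3 of these 6 rose and the other 5 did not pass the test. The corrected fit also repeated the normalisation on its own genes. Ttr, at 1585 times the background of the miR-206 libraries, went from -2.38 to 0.48, and Gstp1, at 93.0 times, from -5.70 to -2.80. Subtraction takes little from such genes, so rises after correction cannot be credited to background removal alone.

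With the counts as deposited, Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327) fell from 1481 ± 1201 to 5.80 ± 1.27 CPM (SD, n = 3 each), a log2 fold change of -7.99 (SE 1.17, edgeR adjusted p = 0.000543). G0s2 (ENSMUSG00000009633, chromosome 1, 193272161 to 193273217) fell from 239 ± 170 to 2.33 ± 0.843 CPM (-6.66, SE 0.86, adjusted p = 0.000353). Sds (chromosome 5) fell from 704 ± 489 to 8.70 ± 6.19 CPM (-6.35, SE 0.98, adjusted p = 0.000676), and Cyp4a10 (chromosome 4) from 500 ± 407 to 6.45 ± 3.96 CPM (-6.26, SE 1.15, adjusted p = 0.00165). Control 1 stood apart from the other controls. Its log2 CPM correlated with theirs at 0.887 and 0.890, against 0.981 between them. It counted Mt1 at 727 against 21454 and 18725, G0s2 at 328 against 3372 and 2864, Sds at 1054 against 9494 and 8720 and Cyp4a10 at 234 against 7399 and 6185. All 4 genes passed the test with each library left out in turn. The immunoglobulin genes Igkc (-8.12) and Igha (-6.70), transcribed in plasma cells, fell from 321 ± 27.0 to 1.17 ± 0.914 and from 292 ± 48.4 to 2.81 ± 2.18 CPM. Mt2 was counted at 31, 1894 and 1843 in the controls and at 7, 0 and 0 in the miR-206 libraries, near their background, so no fold is given. The last 3 of the 10 largest falls rest on 1 or 2 counts over all miR-206 libraries. Their ratio of miR-206 to control was 0.00450 (95% counting interval 0.000543 to 0.0163) for Iglv1, 0.00401 (0.000101 to 0.0225) for the cytotoxic granule gene Nkg7 and 0.00415 (0.000105 to 0.0233) for the B cell chemokine Cxcl13. All 10 kept their direction and passed the test under all 7 treatments of scale and background that were compared for named genes. Mt1 and Mt2, and the immunoglobulin genes, are close paralogs whose reads can be shared.

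The 10 largest rises were genes of low level. Chrna3, a subunit of the nicotinic acetylcholine receptor (ENSMUSG00000032303, chromosome 9, 55010111 to 55026562), rose from 1.45 ± 1.30 to 14.97 ± 2.40 CPM (3.34, SE 0.59, adjusted p = 0.00138). The mitochondrial tRNA gene mt-Tv rose from 8.88 ± 6.19 to 89.3 ± 8.48 CPM (3.33), and mt-Th from 4.15 ± 2.59 to 32.2 ± 3.46 CPM (2.97). Speer4cos (3.29), the receptor gene Olfr1269 (3.26), the sugar transporter gene Slc5a4b (3.20), the cardiac kinase gene Tnni3k (3.18), the organic anion transporter gene Slc22a13 (3.18), the deiodinase gene Dio2 (3.05) and the pannexin gene Panx3 (3.03) completed the 10, with 9.11 to 17.0 CPM in the miR-206 libraries. All 10 passed the test under the same 7 treatments. Of 749 receptor genes tested as background, 372 rose and 1 fell, with a median of 1.68, and Chrna3, Olfr1269, Slc5a4b, Tnni3k, Dio2 and Panx3 lay at 2.26 to 5.36 times the background of the miR-206 libraries. Speer4cos and Slc22a13 lay further above it, at 22.6 and 12.4 times.

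Ttr, the gene of the thyroid hormone carrier transthyretin and the source of the vector's promoter (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), fell from 6778 ± 4128 to 1300 ± 747 CPM (-2.38, SE 0.76, adjusted p = 0.0231) with the counts as deposited. It passed in 2 of the 6 fits with 1 library left out and under 2 of the 7 treatments. Its value was 0.48 (SE 0.51, adjusted p = 0.469) after background correction and 0.42 with libraries scaled on hepatocyte identity genes, of which it is 1, a scale on which the median of all genes is 2.80. Ptpn1, a phosphatase of the insulin receptor (chromosome 2, 167932057 to 167979385), fell with a value of -2.72 (SE 0.54, adjusted p = 0.00249), which was -1.19 (SE 0.94, adjusted p = 0.332) after correction and 0.14 with hepatocyte scaling. Nr1h3, the oxysterol receptor that induces lipogenesis (chromosome 2, 91184061 to 91202834), fell from 120 ± 77.4 to 8.08 ± 2.99 CPM (-3.90, SE 0.66, adjusted p = 0.00105), and its value was -1.35 (SE 0.48, adjusted p = 0.0535) after correction. Klf4 did not pass the test, at 3.80 ± 2.41 and 2.10 ± 1.13 CPM (adjusted p = 0.279).

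In all, 13502 of 24382 genes passed the edgeR test, of which 6289 rose and 7213 fell, around a median log2 fold change of 0.45 over all tested genes. Genes that rose were 51.0% protein-coding with medians of 1.26 CPM in controls and 5.16 CPM in miR-206 cells, and genes that fell were 95.7% protein-coding with medians of 29.5 and 6.37 CPM. The split between rises and falls depended on the scale. It was 10629 to 4812 with upper-quartile factors (median 1.25), 11642 to 3774 with library size alone (1.47), and 15588 to 424 with hepatocyte scaling (2.80), or 9492 to 1184 when the background was also subtracted (2.27), against 0.35 for the median with RLE factors. Without miR-206 replicate 1 or 3 the total was 8796 or 8472. The number that rose was 2109, 2966 and 1916 without miR-206 replicates 1, 2 and 3, 4185 without control replicate 3 and 10674 without control replicate 1.

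After background correction, 2505 of 6458 expressed protein-coding genes passed, of which 1194 rose and 1311 fell, around a median of -0.23. All 1311 that fell had also fallen with the counts as deposited, whereas of the 1194 that rose 38 had risen, 438 had fallen and 718 had not passed. The split was 453 to 1718 with library size alone (median -0.74) and 963 to 631 with hepatocyte scaling (median -0.0018). RLE and upper-quartile factors gave medians of -0.32 and -0.29. All 183 list members called in the corrected fit kept their direction under all 5 scalings, and 88 passed the test under all 5. With each of the 6 libraries left out in turn, 77 passed. All 5 scalings used the same subtracted and filtered genes, so they do not test the direction against the counts as deposited. Of the 71 list members that rose, 1 had risen, 25 had fallen and 45 had not passed with those counts. All 112 that fell had also fallen with them. The total was 1485 and 1382 without control replicates 2 and 3. Of the corrected genes, 175 (2.71%) lay at or under background in all 3 miR-206 libraries and 0 in all 3 controls, and no fold is given for these. The 10-fold minimum was averaged over all 6 libraries, and the controls had the lower background. Genes could thus pass through the controls alone, and the filter by itself can give this imbalance. Some other corrected folds rest on few counts above background, and the SE leaves out the error of the subtraction. In the miR-206 libraries H2-Aa, Smarcd2, Cdkn1a and Tkt lay at 1.44, 1.44, 1.53 and 1.83 times the background.

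**Figure D2:**
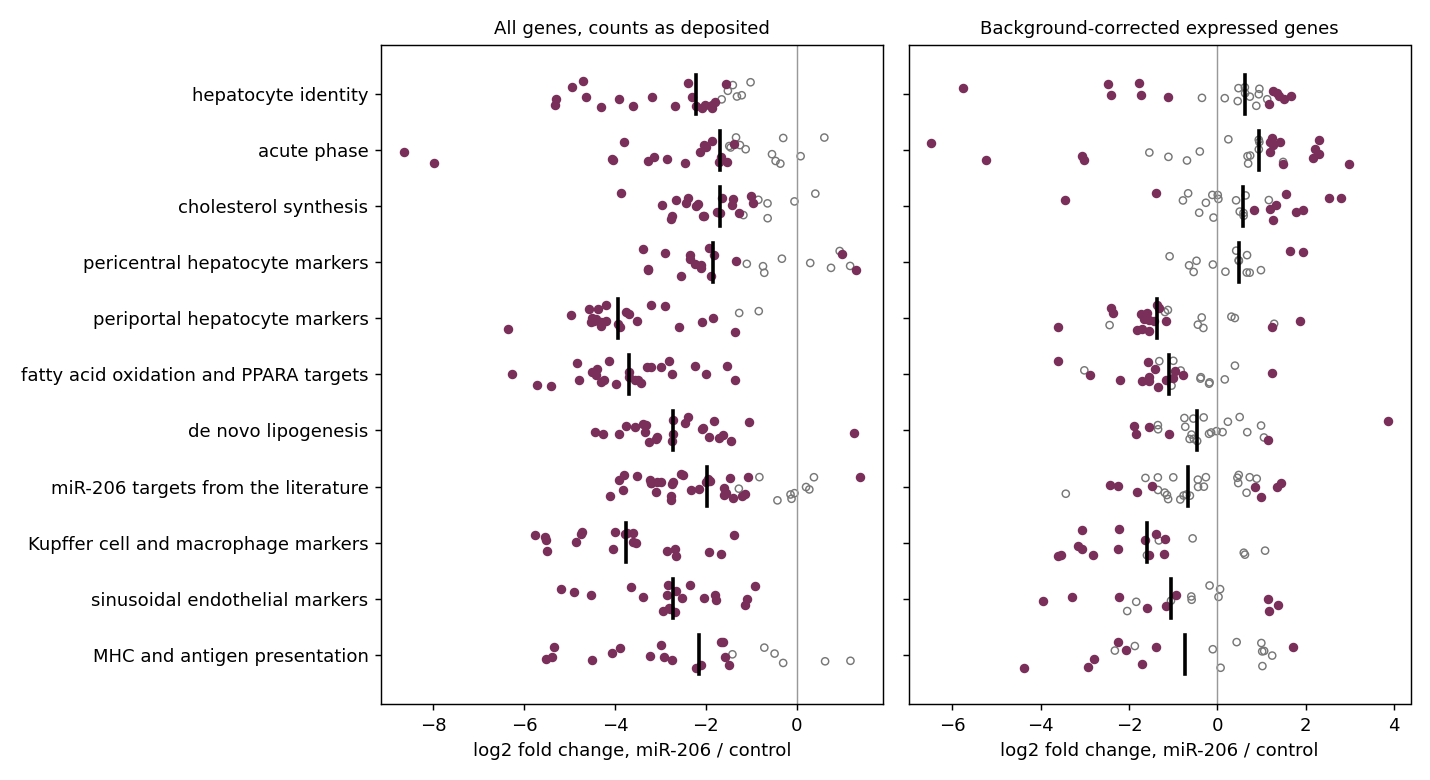
Log2 fold change of miR-206 against control (x axis) of the members of 11 gene lists, with the counts as deposited (left) and after background correction (right), 1 point per gene, filled when past the edgeR test at adjusted p under 0.05, and black bars at list medians. Members at or under background in all miR-206 libraries count in the medians but are not drawn on the right. The Kupffer median is -3.76 on the left and -1.60 on the right, whereas that of hepatocyte identity is -2.22 on the left, 0.62 on the right, 0.49 with uncorrected counts scaled on its own genes and -0.02 with corrected counts scaled by library size alone.

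With the counts as deposited, 26 of the 29 lists lay lower than the other genes by camera (adjusted p from 5.3e-09 to 0.0464). Scaling libraries on hepatocyte identity genes shifts all genes, with a median that moves from 0.45 to 2.80, and so cannot test where a list lies among them. On that scale 21 of the 29 list medians, 19 of them among the 26, turned from negative to positive. Each list's median on that scale follows its first median below, and bears on the direction against hepatocyte identity genes, not against all genes. With an estimated correlation none of the 29 passed (lowest adjusted p = 0.214, and 4 lists at an unadjusted p under 0.05), whereas 25 passed fry's directional test. After correction 1 of 27 lists passed camera, Kupffer cells, and none did with an estimated correlation (0 at an unadjusted p under 0.05). List examples outside the rule for named genes were chosen after their values were seen.

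Fatty acid oxidation and Ppara targets, which burn fat in mitochondria and peroxisomes, fell in 26 of 26 tested members (26 adjusted over the list alone), with a median of -3.69, or -0.71 with hepatocyte scaling. After correction 14 of 26 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -1.10 (camera adjusted p = 0.0735), and 4 fell with corrected counts scaled on hepatocyte identity genes. Among them Cpt1a, which admits fatty acids to mitochondria, fell with a corrected value of -2.89 (SE 0.59), Ehhadh of peroxisomal oxidation with -2.19 (SE 0.60), Hadha with -1.16 (SE 0.24) and Acadvl with -1.55 (SE 0.40), and Vnn1 rose with 1.23. The last 3 passed the test under 4 of 5 scalings, and no member rose in 5 of the 6 fits with 1 library left out. The number that fell was 5, 5, 7 and 2 without control replicates 2 and 3 and miR-206 replicates 1 and 3. The miR-206 libraries in which these genes fell are those with the higher background, and 2 of the 3 have the higher mitochondrial shares.

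Periportal hepatocyte markers, of urea synthesis, amino acid breakdown and glucose output, fell in 23 of 25 members (24 adjusted over the list alone), with a median of -3.94, or -0.92 with hepatocyte scaling. After correction 14 fell and 2 rose (16 and 3 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 0.0988), and 6 fell with corrected counts scaled on hepatocyte identity genes. Hsd17b6 fell with a corrected value of -2.36 (SE 0.33), Id3 with -2.41 (SE 0.48), Cyp2f2 with -1.82 (SE 0.32), and the urea cycle enzymes Ass1, Asl and Arg1 with -1.32, -1.54 and -1.56 (these 3 past under 4 of 5 scalings), while Apof (1.87) and Vnn1 rose. The number that fell was 9, 8 and 4 without control replicates 2 and 3 and miR-206 replicate 3, and 1 to 4 rose with 1 library left out. Pericentral markers fell in 14 of 24 members (14 adjusted over the list alone) and the 2 genes Lgr5 (1.31) and Slc22a3 (1.00) rose, with a median of -1.85, or 1.08 with hepatocyte scaling. After correction 2 of 15 rose (2 adjusted over the list alone), Cyp7a1 (1.65) and Lect2 (1.94), and none fell (2 to 4 and 0 to 1 with 1 library left out), with a median of 0.48, or -0.07 by library size alone (camera adjusted p = 0.418). Glul, the glutamine synthetase of the central vein, had a corrected value of -0.64 (adjusted p = 0.152).

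Hepatocyte identity genes fell in 19 of 25 members (21 adjusted over the list alone), with a median of -2.22, which lay 2.67 below that of all genes (camera adjusted p = 8.5e-08, and 0.289 with an estimated correlation). Hepatocyte scaling holds this list's own mean near 0 by construction. After correction 6 of 24 rose and 7 fell (7 and 7 adjusted over the list alone). The corrected median was 0.62, or -0.02 by library size alone, and the mean was -0.38 (camera adjusted p = 0.579, direction up). The members that rose encode plasma proteins, among them prothrombin (F2, 1.68, SE 0.41) and Apoh (1.50, SE 0.40). Those that fell include the urea cycle enzyme Cps1 (-2.47, SE 0.55), tryptophan dioxygenase Tdo2 (-2.41, SE 0.64) and the transcription factor Hnf4a (-1.78, SE 0.42). The transcription factors Foxa2 and Cebpa, with 59 to 139 and 70 to 535 counts in the controls, had 2 to 3 and 8 to 16 counts in the miR-206 libraries, below the mean background. The number that rose was 12 without miR-206 replicate 2, 0 without control replicate 2, control replicate 3 or miR-206 replicate 3, 1 without control replicate 1 and 3 without miR-206 replicate 1. The number that fell was 4 without control replicate 2, miR-206 replicate 1 or miR-206 replicate 3.

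Acute phase genes fell in 17 of 28 members (20 adjusted over the list alone), with a median of -1.68, or 0.86 with hepatocyte scaling. After correction 11 of 27 rose and 4 fell (13 and 5 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 0.0897), and 0.34 by library size alone (adjusted p = 0.0224). With an estimated correlation the first adjusted p was 0.902, and the other scale was not tested that way. The fibrinogen chains Fga, Fgb and Fgg rose with 2.31 (SE 0.45), 2.30 (SE 0.42) and 2.17 (SE 0.42), and serum amyloid P, Apcs, with 2.20 (SE 0.39). Their values with the counts as deposited were -0.30, -0.36, -0.46 and -0.54, none past the test. Mt1, Mt2, the endotoxin receptor gene Cd14 and lipocalin Lcn2 were the 4 that fell, a number that was 2 without control replicate 2, control replicate 3 or miR-206 replicate 3. The number that rose was 4, 4, 5, 16, 5 and 7 without control replicates 2 and 3, miR-206 replicates 1, 2 and 3 and control replicate 1.

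Cholesterol synthesis genes fell in 19 of 25 members (19 adjusted over the list alone), with a median of -1.68, or 0.86 with hepatocyte scaling. After correction 9 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.148), 0.03 by library size alone. Hmgcs1 of the early pathway rose with 1.93 (SE 0.25) and the sterol oxidase Msmo1 with 2.52 (SE 0.42). Lanosterol synthase Lss, at its background in the miR-206 libraries, was among those that fell. The number that rose was 3 without control replicates 2 or 3 or miR-206 replicates 1 or 3, and 6 without miR-206 replicate 2, and 1 to 2 fell with 1 library left out. In all, 5 rose and 1 fell with corrected counts scaled on hepatocyte identity genes.

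Lipogenesis genes fell in 24 of 25 members and Pnpla3 rose (24 and 1 adjusted over the list alone), with a median of -2.73, or -0.04 with hepatocyte scaling. After correction 4 fell and 2 rose (4 and 2 adjusted over the list alone, 2 to 5 and 1 to 3 with 1 library left out, 2 and 1 with corrected counts scaled on hepatocyte identity genes), with a median of -0.46 (camera adjusted p = 0.735). Fatty acid synthase Fasn (-1.88, SE 0.33), Lpin1 (-1.85), the lipid droplet coat gene Plin2 (-1.55) and the desaturase gene Fads1 (-1.09) fell, and Pnpla3 (3.86, SE 0.41) and acetyl-CoA carboxylase Acaca (1.14) rose. Acaca fell with the counts as deposited (-1.04). The lipogenic regulator Srebf1 had a corrected value of -0.54 (adjusted p = 0.215). Insulin signalling and glucose output fell in 20 of 23 members (21 adjusted over the list alone), with a median of -2.55, or 0.14 with hepatocyte scaling. After correction 5 of 19 fell and 2 rose (5 and 2 adjusted over the list alone), with a median of -0.72. The number that fell was 2, 2, 3 and 1 without control replicates 2 and 3 and miR-206 replicates 1 and 3, and 1 with corrected counts scaled on hepatocyte identity genes. Between 0 and 3 rose with 1 library left out. The gluconeogenic enzyme genes Fbp1 (-1.78, SE 0.35) and Pck1 (-1.59), Tat (-1.73), glycogen synthase Gys2 (-1.38) and Creb3l3 (-1.30) fell, and Ppargc1a (1.18) and Gsk3b (1.30) rose. The pentose phosphate pathway fell in 7 of 8 members and Rpia rose (7 and 1 adjusted over the list alone), with a median of -2.41, or 0.45 with hepatocyte scaling. After correction 1 of 7 fell, transketolase Tkt (-2.24, SE 0.64), and 0 adjusted over the list alone (0 to 2 with 1 library left out), with a median of -0.31.

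Bile acid synthesis and transport fell in 16 of 19 members (17 adjusted over the list alone), with a median of -2.55, or 0.18 with hepatocyte scaling. After correction 5 of 19 rose and 2 fell (2 and 0 adjusted over the list alone, 1 to 4 and 0 to 3 with 1 library left out, 4 and 0 with corrected counts scaled on hepatocyte identity genes), with a median of 0.03 that was negative with RLE factors (-0.06), upper-quartile factors (-0.03) and library size alone (-0.54). Cyp7a1 (1.65), Cyp8b1 (1.15) and the uptake transporter genes Slc10a1, Slco1a4 and Slco1b2 (1.29, 1.39 and 1.52) rose, and Cyp27a1 (-1.01) and the bile acid receptor gene Nr1h4 (-0.75) fell. Xenobiotic metabolism fell in 19 of 33 members (19 adjusted over the list alone), with a median of -2.25, or 0.83 with hepatocyte scaling. After correction 8 of 28 rose and 6 fell (9 and 8 adjusted over the list alone, 4 to 9 and 4 to 7 with 1 library left out), with a median of 0.15, -0.40 by library size alone, and a mean of -0.13. Ugt1a1 (2.37), Gsta2 (2.27) and Cyp2b9 (3.07) rose, and Gstp1 (-2.80), Sult1a1 (-1.99) and Por (-1.76) fell. Male-biased genes fell in 19 of 20 members (19 adjusted over the list alone), with a median of -2.70, or 0.0021 with hepatocyte scaling. After correction 3 rose (Elovl3, C6 and Ugt2b1) and 2 fell (Gstp1 and Mup20), 3 and 2 adjusted over the list alone and 1 to 4 and 1 to 3 with 1 library left out, with a median of -0.23 and a camera direction of up (adjusted p = 0.935).

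Antigen presentation genes fell in 16 of 22 members (17 adjusted over the list alone), with a median of -2.15, or 0.60 with hepatocyte scaling. After correction 7 of 18 fell and Cd86 rose (7 and 2 adjusted over the list alone, 6 to 8 and 0 to 6 with 1 library left out), with a median of -0.74 (camera adjusted p = 0.579). H2-Ab1 (-2.93, SE 0.35), the invariant chain Cd74 (-2.80, SE 0.43), H2-Eb1 (-2.25, SE 0.30) and H2-Aa (-4.38, SE 0.75) of class II, and the immunoproteasome subunit genes Psmb8 (-2.07) and Psmb10 (-1.71), passed under all 5 scalings and with any library left out. Interferon-stimulated genes fell in 21 of 33 members (21 adjusted over the list alone), with a median of -1.30, or 1.30 with hepatocyte scaling. After correction 7 of 25 rose, among them Oasl2 (1.70), Usp18 (1.33) and Cxcl10 (1.99), and Psmb8 and Irf7 (-1.67) fell (7 and 2 adjusted over the list alone), with a median of 0.23, -0.22 by library size alone. Without control replicate 2 or 3, 2 rose, and 1 to 3 fell with 1 library left out. Chemokines and cytokines fell in 12 of 27 members, and Il6 (1.78) and Il12b (1.63) rose (12 and 2 adjusted over the list alone), with a median of -0.45 that was 0.36, 0.55 and 1.88 with upper-quartile factors, library size alone and hepatocyte scaling. After correction Cxcl9 (2.24) and Cxcl10 rose and Ccl6 (-2.65), Mif (-1.54), Hmgb1 (-0.67) and Cxcl13 fell among 13 (3 and 4 adjusted over the list alone, 1 to 2 and 2 to 6 with 1 library left out), with a median of -0.52.

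Immediate early and heat shock genes fell in 22 of 28 members (23 fell and 1 rose adjusted over the list alone), with a median of -2.39, or 0.07 with hepatocyte scaling. After correction the 3 chaperone genes Hsp90aa1 (-2.57, SE 0.30), Hspa8 (-2.38, SE 0.33) and Hsph1 (-1.43, SE 0.26) fell among 17 (3 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.239). Unfolded protein and integrated stress response genes fell in 16 of 21 members (16 adjusted over the list alone), with a median of -2.19, or 0.52 with hepatocyte scaling. After correction Herpud1 (-1.93, SE 0.31), Atf4 (-1.46) and Atf5 fell and the chaperone Calr (1.61) rose among 20 (3 and 1 adjusted over the list alone, 2 to 5 and 0 to 6 with 1 library left out), with a median of 0.04 that was negative with RLE factors (-0.05), upper-quartile factors (-0.02) and library size alone (-0.54), and a mean of -0.16. p53 targets fell in 14 of 19 members, and Zmat3 and Tnfrsf10b rose (15 and 3 adjusted over the list alone), with a median of -1.67, or 0.91 with hepatocyte scaling. After correction Cdkn1a (-2.43, SE 0.45) and Sesn1 fell among 11 (1 adjusted over the list alone, 1 to 3 with 1 library left out, 3 rose without control replicate 1, and 1 fell with corrected counts scaled on hepatocyte identity genes), with a median of 0.29, -0.26 by library size alone, and a mean of -0.53. Fetal and injury markers fell in 17 of 20 members and Afp (1.43) rose (17 and 1 adjusted over the list alone), with a median of -3.07, or -0.75 with hepatocyte scaling. After correction Tubb2a, Ly6d, Spp1, Krt19 and Krt8 fell among 16 (4 adjusted over the list alone, 2 to 8 with 1 library left out), with a median of -1.74 (camera adjusted p = 0.109). Spp1 and Krt19 are also cholangiocyte markers, counted highest in control 1 (Krt19 at 1180 against 457 and 537). Without control replicate 1, 3 of these markers fell and 1 rose. Cell cycle genes fell in 10 of 27 members and Top2a, Bub1 and Foxm1 rose (9 and 2 adjusted over the list alone), with a median of -0.56 that was 0.36, 0.59 and 2.28 with upper-quartile factors, library size alone and hepatocyte scaling (camera adjusted p = 0.105). After correction Tyms (3.31, SE 0.34) rose and Mcm7 fell among 6 (1 and 1 adjusted over the list alone), with a median of -0.94. No cell cycle gene fell in 5 of the 6 fits with 1 library left out, or with corrected counts scaled on hepatocyte identity genes. None of 13 mitochondrially encoded genes passed (0 adjusted over the list alone), with a median of 0.32, or 2.62 with hepatocyte scaling (camera adjusted p = 0.859, direction down, and up by library size alone).

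Whether transcripts with sites for miR-206 were lower was asked of predicted and of published targets. The predicted targets were not: genes whose 3' UTR holds an 8mer or 7mer-m8 seed site had a mean log2 fold change 0.18 above that of other genes (1967 against 14992 genes, camera adjusted p = 0.433 over the 2 fits). After background correction the difference was 0.22 (639 against 5799 genes, camera adjusted p = 0.344). Adjusted for UTR length, these differences were 0.0054 and 0.068. The seed match ACATTCC stood at the 58.5th percentile of 16013 sequences of 7 bases ranked from the lowest mean, and at the 65.5th percentile of 13825 after correction. Among 40 published targets, 30 fell and the Wnt antagonist Sfrp1 rose (31 and 1 adjusted over the list alone), with a median of -1.97, or 0.53 with hepatocyte scaling (camera adjusted p = 6.1e-08, and 0.214 with an estimated correlation). After correction 4 of 30 fell and 4 rose (3 and 4 adjusted over the list alone, 2 to 5 and 1 to 7 with 1 library left out), with a median of -0.66 (camera adjusted p = 0.735). The chromatin remodeller subunit Smarcd2 (-2.44, SE 0.49), Tkt (-2.24), the actin-binding Tagln2 (-1.81) and the chaperonin Hspd1 (-1.49, SE 0.26) fell, and Fn1 (1.43), Gpd2 (1.35), the hepatocyte growth factor receptor gene Met (0.99) and Arcn1 (0.85) rose. Of the 20 corrected targets with a site in the annotated UTR, 3 fell and 4 rose. Their median was -0.73 against -0.28 for the published targets without a site, a difference that was not tested.

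Markers of other liver cells were compared because the sort was on GFP alone. Kupffer cell and macrophage markers fell in 20 of 20 members (20 adjusted over the list alone), with a median of -3.76, or -1.01 with hepatocyte scaling. After correction 13 of 19 fell and none rose (14 adjusted over the list alone), with a median of -1.60 (camera adjusted p = 0.0133). That adjusted p was 0.902 (p = 0.095) with an estimated correlation, and it ran from 0.0053 to 0.0224 over 5 scalings. The complement genes C1qa (-3.61, SE 0.54), C1qb (-3.17, SE 0.42) and C1qc (-3.55, SE 0.61), the lectin Clec4f (-3.07, SE 0.39) and the complement receptor gene Vsig4 (-2.81, SE 0.46), all typical of resident macrophages, passed under all 5 scalings and with any library left out. Their summed CPM was 2013 ± 985 in controls and 117 ± 6.91 in miR-206 libraries (log2 difference -3.95, n = 3 each, exact permutation p = 0.1, the smallest possible, adjusted p = 0.114), and 1469 ± 275 and 438 ± 57.7 after correction (-1.73, exact p = 0.1).

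Sinusoidal endothelial markers fell in 20 of 20 members (20 adjusted over the list alone), with a median of -2.73, or -0.17 with hepatocyte scaling. After correction 8 of 19 fell, among them the lectin Clec4g (-3.30, SE 0.77) and the water channel Aqp1 (-3.95, SE 0.73), and Stab2 (1.38), Pecam1 (1.16) and Kdr (1.14) rose (10 and 3 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 0.237). Clec4g and Aqp1 lay at 1.94 and 1.25 times the background of the miR-206 libraries, so their folds rest on few counts. The number that fell was 5, 4 and 5 without control replicates 2 and 3 and miR-206 replicate 3, and 4 with corrected counts scaled on hepatocyte identity genes. Between 1 and 4 rose with 1 library left out. The summed CPM was 1062 ± 6.54 and 194 ± 16.6 (-2.45, n = 3 each, exact p = 0.1), and 886 ± 406 and 626 ± 36.7 after correction (-0.41, exact p = 0.3). Control 1 carries the corrected difference in these endothelial sums, at 1354 CPM against 644 and 658 in the other controls and 599 to 668 in the miR-206 libraries. With hepatocyte scaling of uncorrected counts the difference in sums was 0.20. Stellate and fibroblast markers fell in 14 of 19 members (14 adjusted over the list alone), with a median of -2.09, or 0.47 with hepatocyte scaling. After correction Bgn (-1.57), Colec11 (-1.58) and Dcn (-1.03) fell and the pericyte gene Rgs5 (1.85) rose among 12 (4 and 2 adjusted over the list alone, 1 to 5 and 1 to 2 with 1 library left out, and no falls with corrected counts scaled on hepatocyte identity genes), with a median of -0.65. Cholangiocyte markers fell in 10 of 13 members (10 adjusted over the list alone), with a median of -2.66, or -0.67 with hepatocyte scaling. After correction Spp1 (-2.73) and Krt19 (-2.72) fell and Slc4a4 (0.98) rose among 8 (2 and 1 adjusted over the list alone), with a median of -1.94. Control 1 carries much of this list, with a corrected sum of 4387 CPM against 593 and 740 in the other controls and Spp1 counts of 21072 against 7471 and 8289. None fell without control replicate 1, where 3 rose, and none fell without any 1 miR-206 replicate.

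Lymphocyte markers fell in 9 of 21 members and 3 rose, Cd3e and Ms4a1 among them (9 and 3 adjusted over the list alone), with a median of -0.77 that was 0.13, 0.15 and 2.11 with upper-quartile factors, library size alone and hepatocyte scaling. After correction 2 members were left, of which Nkg7 fell (1 adjusted over the list alone). Neutrophil, monocyte and dendritic markers fell in 5 of 20 members (Ly6c2, Plac8 and Lcn2 among them), and Ccr9 and 1 of 2 genes listed as Itgam (ENSMUSG00000108596, 2.28) rose (5 and 2 adjusted over the list alone), with a median of -0.43 that was 0.43, 0.60 and 2.01 on those 3 scales (camera adjusted p = 0.196, fry adjusted p = 0.0338). After correction the neutrophil gene Retnlg (4.37) and Cd209a (2.08) rose and Ly6c2 and Lcn2 fell among 8 (4 and 2 adjusted over the list alone), with a median of 1.02. With 1 library left out 2 to 4 rose and 0 to 2 fell, none of them falling without control replicate 2 or 3. Red cell and platelet transcripts fell in 3 of 9 members, Ppbp, Alas2 and Itga2b (3 adjusted over the list alone), with a median of -1.22, or 1.59 with hepatocyte scaling (camera adjusted p = 0.0464, but 0.381 with an estimated correlation, and fry adjusted p = 0.0867). After correction Ppbp fell among 6 (0 adjusted over the list alone, and none in 5 of the 6 fits with 1 library left out), with a median of 1.37, a mean of -0.27 and a camera direction of down. Summed CPM differed by -2.28 for stellate, -3.62 for cholangiocyte, -2.16 for lymphocyte, -0.65 for neutrophil, -1.98 for red cell and -2.06 for hepatocyte identity genes (n = 3 each, exact permutation p = 0.1 each, 0.2 for red cells). After correction these were -0.52, -1.70, no value, 0.75, 0.32 and 0.61, the lymphocyte sum being 0 in 1 library.

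**Figure D3:**
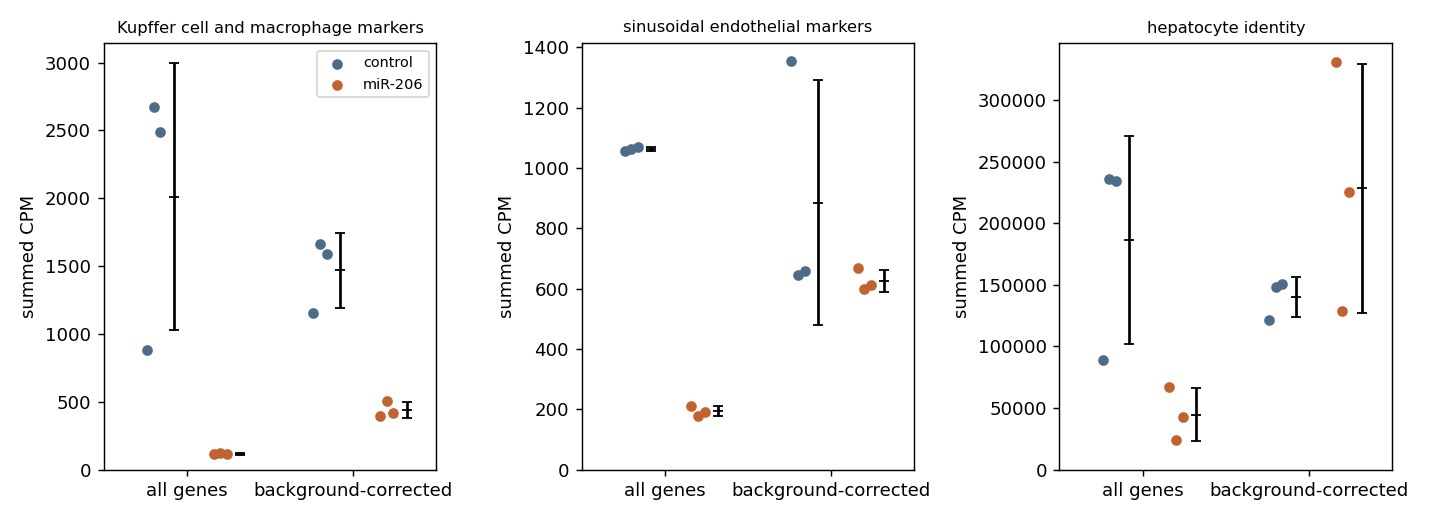
Summed CPM of Kupffer cell, sinusoidal endothelial and hepatocyte identity genes (y axes, each from 0) with all genes and after background correction, 1 point per library, controls in blue and miR-206 in orange, with mean and SD bars (n = 3). The Kupffer sums do not overlap between groups on either scale, whereas the hepatocyte identity sums are lower in miR-206 libraries with all genes (-2.06) and overlap the controls after correction (0.61).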

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

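The alternatives that subtract the background, ask for a multiple of it, scale on hepatocyte identity genes or keep libraries of low mitochondrial share, all those of the background-corrected fit, and the list tests with upper-quartile factors or library size only were chosen after seeing the data. For each result below that did not hold, the cause was not tested. The miR-206 libraries hold 4157947 to 5724329 counts, and a gene under 0.524 to 0.722 CPM has fewer than 3 counts there. Of simulated changes between 3 and 3 libraries with all genes, 0 of 87 at 2-fold and 34 of 87 at 4-fold were recovered. With background-corrected expressed genes it was 3 of 99 and 44 of 95. Few simulated genes were changed, unlike in the data, so these shares do not give the sensitivity here. Genes not past the test may still differ.

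For genes changed, miR-206 against control (13502), the count was 12059 with the replicate block and 13074 with DESeq2. It was 2505 for background-corrected expressed genes, 4168 for genes at least 10 times the background of all types and 3774 for these after subtraction. Leaving out 1 library gave 8472 to 19532 (without miR-206 replicate 3 and without control replicate 1). For genes changed, background-corrected expressed genes (2505), the count was 2267 with the replicate block, 4436 at 5 times the background, 1308 at 20 times and 1594 when scaled on hepatocyte identity genes. It was 4765 in the low mitochondrial share libraries (2 controls, 1 miR-206 library, whose spread is taken from the controls). Leaving out 1 library gave 1382 to 2740. For gene list tests, miR-206 against control (26 lists), the count was 0 with an estimated correlation, 1 for background-corrected expressed genes, 6 and 4 for genes at 10 times the background before and after subtraction, and 17 when background subtracted and scaled on hepatocyte identity genes. For gene list tests, background-corrected expressed genes (1 list, Kupffer cells), the count was 0 with an estimated correlation, 5 with the replicate block, 2 with library size only, 3 in the low mitochondrial share libraries, and 1 to 3 with 1 library left out. Kupffer cells passed in each of these except with the estimated correlation. Fatty acid oxidation, periportal, acute phase and fetal markers joined with the block. Fatty acid oxidation and periportal markers joined without control replicate 1, fatty acid oxidation and acute phase genes without miR-206 replicate 2 and in the low mitochondrial share libraries, and acute phase genes with library size only. The miR-206 seed site genes stayed above the others under every alternative run, but by 0.0054 with all genes and 0.068 after correction once UTR length was allowed for.

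Scaled on hepatocyte identity genes, with the counts as deposited, the median of all genes moved from 0.45 to 2.80, so that list medians on this scale tell the direction against hepatocyte identity genes only. They do not test where a list lies among all genes. For 19 of the 26 lists they turned, to 0.53 for miR-206 targets from the literature, 0.86 for cholesterol synthesis, 0.14 for insulin signalling and glucose output, and 0.45 for pentose phosphate pathway. Liver lists turned to 0.49 for hepatocyte identity, 1.08 for pericentral hepatocyte markers, 0.18 for bile acid synthesis and transport, 0.83 for xenobiotic metabolism, and 0.0021 for male-biased liver genes. Defence and stress lists turned to 0.86 for acute phase, 1.30 for interferon-stimulated genes, 1.88 for chemokines and cytokines, 0.60 for MHC and antigen presentation, 0.071 for immediate early and heat shock, 0.52 for unfolded protein and integrated stress response and 0.91 for p53 targets. Other cell types turned to 0.47 for stellate cell and fibroblast markers, 2.11 for lymphocyte markers and 1.59 for red cell and platelet transcripts. Marker sums turned to 0.20 for sinusoidal endothelial, 0.38 for stellate, 0.50 for lymphocyte, 2.01 for neutrophil, monocyte and dendritic and 0.67 for red cell markers and to 0.60 for hepatocyte identity. Of 106 named genes 10 turned, all still below 2.80: Ttr (0.42), Ptpn1 (0.14), Klf4 (1.18), Lss (0.12), Mcm7 (0.098), Rrm2 (0.15), Abcc3 (0.0041), Plac8 (1.09), Alas2 (0.16) and Itga2b (0.84). A further 48 kept their direction and no longer passed.

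Background subtracted and scaled on hepatocyte identity genes, the median of all genes was 2.27, and of the 15 of the 26 lists whose medians turned, camera stayed down for all but pericentral hepatocyte markers, past the test for 6. Medians turned to 0.86 for cholesterol synthesis, 0.29 for pentose phosphate pathway, 0.92 for hepatocyte identity, 1.02 for pericentral hepatocyte markers, 0.43 for bile acid synthesis and transport, 0.73 for xenobiotic metabolism, and 0.16 for male-biased liver genes. The others turned to 1.28 for acute phase, 0.94 for interferon-stimulated genes, 1.59 for chemokines and cytokines, 0.46 for unfolded protein and integrated stress response, 0.83 for p53 targets, 0.055 for stellate cell and fibroblast markers, 1.05 for lymphocyte markers and 1.81 for red cell and platelet transcripts. Marker sums turned to 0.24 for stellate, 0.35 for lymphocyte, 1.95 for neutrophil and 0.68 for red cell markers and 1.01 for hepatocyte identity. The genes Ttr (0.85), Gulo (0.024), Abcc3 (0.12), Plac8 (1.31) and Alas2 (0.38) turned, all still below 2.27.

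Among background-corrected expressed genes, the median or test direction turned, with medians of 0.59 for cholesterol synthesis, 0.62 for hepatocyte identity, 0.48 for pericentral hepatocyte markers, 0.033 for bile acid synthesis and transport, 0.15 for xenobiotic metabolism, and -0.23 for male-biased liver genes. They were 0.94 for acute phase, 0.23 for interferon-stimulated genes, 0.042 for unfolded protein and integrated stress response, 0.29 for p53 targets and 1.37 for red cell and platelet transcripts. Marker sums turned to 0.75 for neutrophil and 0.32 for red cell markers and 0.61 for hepatocyte identity. The lymphocyte sum had no value, and Ttr (0.48) and Plac8 (0.91) turned. With genes of all types at least 10 times the background, these were 0.12 for cholesterol synthesis, 0.21 for acute phase, -0.018 for interferon-stimulated genes, 0.76 for red cell and platelet transcripts and 0.35 for Plac8. After subtraction they were 0.28 for cholesterol synthesis, 0.35 for hepatocyte identity, 0.17 for pericentral hepatocyte markers, 0.66 for acute phase, -0.0656 for interferon-stimulated genes, 8.95e-05 for p53 targets, 1.05 for red cell and platelet transcripts, 0.20 for Ttr and 0.62 for Plac8.

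With upper-quartile factors chemokines and cytokines turned to 0.36 and lymphocyte markers to 0.13, and with library size only to 0.55 and 0.15, with Klf4 at 0.25. The median of all genes was 1.25 and 1.47 on these scales. Unscaled CPM gave 0.40 for the neutrophil sum. In the low mitochondrial share libraries the median of mitochondrially encoded genes was -1.32, and Klf4 (0.20), mt-Nd1 (-1.22), mt-Nd4l (-0.0016) and mt-Co1 (-1.58), none past the test before, turned. With 1 library left out mt-Nd4l ran from -0.25 to 1.60 and mt-Co1 from -0.19 to 1.05, negative without miR-206 replicate 2 and, for mt-Nd4l, without control replicate 2. None of the 106 named genes turned with the replicate block, RLE or upper-quartile factors, DESeq2, limma-voom, no filter or the stricter filter.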

Other observations

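The tests of shallow depth, of cell composition and of background for the Kupffer markers were chosen only after the result was seen, as were the background-corrected fit and the classes of transcript compared next.

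After background correction, transcripts of secreted and membrane proteins, which are translated at the endoplasmic reticulum, lay above the others over all genes, though not within every list. Of 1847 genes whose protein has a hydrophobic signal or membrane segment by a Kyte-Doolittle window, 428 rose and 260 fell with a median log2 fold change of 0.17, and of 4590 without such a segment 756 rose and 1050 fell with a median of -0.40. Within hepatocyte identity genes the medians were 0.95 for 15 with a segment and -1.78 for 9 without, and within periportal markers -0.06 for 10 and -1.56 for 15. The median was higher with a segment in 18 of 26 lists and lower in 8. Among the 8 were fatty acid oxidation (-3.01 for 3 against -1.04), Kupffer (-1.64 against -0.35), fetal and injury (-2.55 against -1.65), endothelial (-1.11 against -0.59), stellate (-1.03 against -0.40) and lipogenesis (-0.50 against -0.31). The plasma proteins Fga, Fgb, Fgg, Apcs, F2 and Apoh rose after correction, though none passed the test with the counts as deposited, whereas the cytosolic enzymes Fbp1 and Tat, the mitochondrial enzyme Cps1 and the chaperones Hspa8 and Hsp90aa1 fell. The gap between classes within each library was 0.54, 0.44 and 0.45 in the controls and 1.28, 0.50 and 0.88 in the miR-206 libraries (0.475 ± 0.0591 against 0.888 ± 0.389, SD, n = 3 each, exact permutation p = 0.2), so it was not beyond the spread between libraries. The window thresholds (2.2 over 11 residues, 2.0 over 19) were set after known genes had been looked at.

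This gap between transcript classes was weighed against GC content and length and against cell damage. A loess correction for GC content, exonic length and level moved the difference in medians from 0.572 to 0.458, between the bounds of 0.25 and 0.5 set for each reading, so these biases may account for part of it. Damaged cells that lose cytosolic RNA might show the same gap in control 1, the control with the highest mitochondrial and background shares, and its gap exceeded the mean of the other controls by 0.102, short of the 0.2 set for that reading. Among the miR-206 libraries, looked at afterwards, the order ran against damage, with a gap of 1.28 at 11.2% mitochondrial counts, 0.88 at 48.7% and 0.50 at 63.8%. Both technical explanations stay open, and so does an effect of miR-206, which was not tested apart from them.

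Genes silent in liver were counted higher in the miR-206 libraries. Raw counts per exonic kb of the receptor genes were 2.53 times those of the controls, with each miR-206 library above each control, which argues against depth and scaling as the cause, since these libraries were the shallower. Genomic DNA of male cells, with a single X, could account for such reads. Protein-coding genes that rose had X to autosome ratios of 0.64, 0.67 and 0.68 in the miR-206 libraries (mean 0.663) against a range of 0.35 to 0.65 set for DNA and a bound of 0.8 against it, so the test did not decide. The controls had 0.50, 0.60 and 0.43.

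Kupffer cell markers were lower in the miR-206 libraries. After correction their median lay below that of hepatocyte identity genes by a log2 difference of -2.221 (bootstrap 95% interval over genes -3.44 to -1.20). This interval holds no spread between libraries. The gap also depends on the measure. Hepatocyte identity genes had a median of 0.62 but a mean of -0.38, and Kupffer markers a mean of -1.68. Kupffer sums after subtraction and hepatocyte scaling did not overlap (654 ± 27.1 and 270 ± 99.5 CPM in control and miR-206 libraries, exact permutation p = 0.1). Background and scaling as treated here thus left a difference, but 3 against 3 libraries cannot exclude them as the cause. The 17 Kupffer markers with a signal or membrane segment lay below all expressed genes of that class, by -1.809 (-3.22 to -1.40, again over genes). A loss of transcripts from outside the endoplasmic reticulum, if alike in all cell types, would not be expected to give this difference. Whether it was alike was not tested. The interval does not cover the spread between libraries, and the class thresholds were set after known genes had been looked at. Such a loss is therefore not excluded. Fewer non-hepatocyte cells among GFP-positive cells could give the lower Kupffer markers. The highest of the Kupffer, endothelial, stellate and cholangiocyte medians lay at -1.276 from hepatocyte identity, which alone met the bound of 0.5 below. The rule was made stricter after this value was seen, because neutrophil (0.39) and red cell (0.75) medians lay above hepatocyte identity. A deficit shared by Kupffer, endothelial, stellate and cholangiocyte markers also depends on the measure. By means, stellate markers (-0.61) lay less than 0.5 below hepatocyte identity (-0.38), with endothelial (-1.904) and cholangiocyte (-1.15) means further below. Sums after subtraction and hepatocyte scaling differed by -1.34 for Kupffer but by -0.03 for endothelial and 0.24 for stellate markers. Cholangiocyte sums overlapped, though lower on average. This explanation thus stays open beside an effect of miR-206.

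Of the 10 ways to split the 6 libraries 3 against 3, 1 gave 13502 changed genes, the real one, and the highest other gave 0 (edgeR, with 7 to 1189 genes at an unadjusted p under 0.05). After correction these were 2505 and 0 (5 to 323 unadjusted, again 1 of 10 as large). Every other split has libraries of both groups on each side, so the group difference falls within the sides and widens their spread. A count of 0 there is thus favoured by the design and lends the real counts no support. The seed site shift was 0.18 in the real split and 0.0656 in the highest other, also 1 of 10. List tests passed for 26 lists in the real split (1 of 10) and for 24 in the highest other. At least 19 passed in every split, although no gene passed in the others. These mixed splits keep part of the group difference between their sides. Their list counts and seed site shifts thus cannot show whether list calls at the preset correlation, or the seed site shift, are specific to the groups. Splits of 10 are too few for a share under 0.05.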
